A study of Mus musculus with 11 samples.

How the data were processed

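The series compared gene expression at 3 postnatal ages in muscle cells sorted by flow cytometry for green fluorescent protein (GFP) from Pax3GFP/+ mice, in which GFP is made from the Pax3 locus. Of the 11 Affymetrix Mouse430_2 arrays, 4 were from postnatal day 1 (P1), 4 from day 12 (P12) and 3 from day 28 (P28). The labels call the arrays of an age biological replicates and do not say how many animals went into each. Per the labels, dead cells were excluded with propidium iodide, and amplified, biotin-labelled cDNA was hybridised to a 3' expression array. Arrays were grouped by the age in their titles. All P28 arrays carry another list of muscles and another suffix in their internal sample names than all P1 and P12 arrays. The internal names of the P28 arrays also begin with the code of P1, while their titles and stated age give P28. Age, muscles and a possible batch therefore coincide for P28, and no batch term could be fitted for it.

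The deposited values are log2 expression values per probe set that the authors made by RMA (background correction, quantile normalization and median polish summary). The labels name Affymetrix Expression Console, RMA and affy without versions, roles or order, so it is not stated whether all arrays were processed alike. The values ran continuously on a log2 scale with similar medians (5.50 to 5.58) and upper quartiles (7.36 to 7.66) on all arrays, and they were used without a further transformation. The lowest value was -0.79 to 0.48 on the P1 and P12 arrays and 1.65 to 2.09 on the P28 arrays, so a separate processing of P28 is not excluded. No column was left out. Arrays give no read depth, and the number of arrays limits the precision.

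Of the 45101 probe sets, 34958 carried exactly 1 gene symbol in the supplied probe annotation, 932 carried several and 9211 carried none. The 64 control probe sets of the manufacturer, 13 of which carried 1 symbol, were not used as genes. The Entrez identifiers of 34754 of the probe sets with 1 symbol were found in the supplied RefSeq gene table, and 0 symbols had to be updated. Each gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. No genome build is given, so no positions are reported. Of 860 list memberships fixed beforehand, 46 had no probe set with that symbol alone.

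Changes between ages were tested with limma 3.58.1 in R 4.3.3, with lmFit on a model of group means over all 11 arrays, contrasts and eBayes (8 residual and 6.62 prior degrees of freedom). The moderated test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over 18193 genes. A gene was said to have risen or fallen at an adjusted p under 0.05. A moderated F test covered any difference among the ages. Log2 changes are given with their SE from the fit, and levels as mean log2 values with the SD over arrays. The test was checked on simulated data with the real residual spread, in which 67, 67 and 66 genes changed by a log2 value of 0.5, 1 and 2. At a log2 change of 1 it recovered 97.0% of them in P12 against P1 and 92.5% in P28 against P12, and at 0.5 it recovered 22.4% and 16.4%.

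Lists of 31 pathways, gene classes and cell types, and a list of sex-linked genes that was only described, were tested with camera on the same fit with its preset inter-gene correlation of 0.01. Its p-values were adjusted over the 93 tests of 31 lists and 3 comparisons. Members that passed the gene test were counted over all genes tested and adjusted over the list alone. The camera test was repeated with an inter-gene correlation estimated from the data for each list. For the lists of cell cycle and quiescent satellite cell genes, the mean per array was compared by exact two-sided permutation tests, adjusted over 6 tests. Genes that passed in both successive steps were counted and set against 100 simulations of unchanged groups, independent lists of the same sizes, and the 6 ways to give each step its own P12 arrays.

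The genes named for a comparison were the 10 with the largest increase and the 10 with the largest decrease among those that passed and whose arrays did not overlap, without gene models lacking a proper symbol, sex-linked genes and receptor or immunoglobulin segments. To these were added up to 4 members of each called list in its direction and up to 2 against it, and in all comparisons Pax3, Pax7, Myf5, Myod1, Myog, Mki67, Cdkn1a, Cdkn1b, Cdkn1c, Calcr, Spry1 and Heyl. Lists of other cell types were also described by the 3 members with the highest mean over all arrays. The groups, tests, lists, this rule and most alternatives were chosen before the data were examined.

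Settings varied as chosen beforehand were median centring, a further quantile normalization, the mean of a gene's probe sets, leaving out dim probe sets, every probe set, leaving out probe sets of the _x_at and _s_at types, array weights, eBayes with trend and robust options, fits of the 2 ages compared alone, other thresholds (adjusted p under 0.01, a log2 change of at least 1), the replicate number as a block, the estimated correlation and leaving out each array in turn. Further alternatives were chosen after seeing the data. These were the difference of the Gapdh 3' and 5' control probe sets as a covariate, an array set (replicates 1 and 2 against 3 and 4 of P1 and P12) as a block and as separate fits, and an exact test of the mean of each list. To see whether equal replicate numbers pair the arrays, deviations from the age means were correlated over genes. In P12 against P1 these correlations were 0.15, 0.27, 0.34 and 0.18 for replicates 1 to 4. Over all pairs of P1 and P12 arrays of 1 array set they ran from 0.14 to 0.34, and between array sets from -0.31 to -0.10. The numbers therefore tracked the array set, and the fit with the replicate number as a block is given beside results named in the text whose call it changed. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.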

Results

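Expression of 18193 genes was measured on 11 arrays of GFP-positive cells from the muscle of Pax3GFP/+ mice at 3 postnatal ages. Satellite cells are the stem cells of skeletal muscle, and Pax3 is a transcription factor of the muscle lineage, so GFP from its locus served as the sort gate. The labels describe proliferating satellite cells of trunk muscle at P1 (n = 4 arrays) and P12 (n = 4 arrays). They describe satellite cells of abdominal, pectoral and intercostal muscle at P28 (n = 3 arrays). The series states that the ages cover proliferating and quiescent satellite cells. Every value is a log2 RMA value of 1 probe set per gene, and changes are log2 differences between ages ± SE.

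The arrays had median log2 values from 5.50 to 5.58, and the bacterial Trp control probe sets, which mark background, averaged 3.36 to 3.64. No pair of arrays was identical (0 pairs). The first principal component held 60.2% of the variance and set the 3 P28 arrays apart from the other arrays, while the second component held 13.1%. Correlations between arrays of 1 age were 0.981 to 0.994, those between P1 and P12 were 0.973 to 0.986, and those of P28 with either age were 0.936 to 0.966. The log2 difference between the Gapdh 3' and 5' control probe sets, a measure of 3' bias in the RNA, was 2.18 ± 0.61 (SD, n = 4) at P1, 2.10 ± 0.88 (SD, n = 4) at P12 and 0.90 ± 0.10 (SD, n = 3) at P28. Within P1 and P12 it was higher in replicates 1 and 2 (2.59 and 2.79 at P1, 2.64 and 3.05 at P12) than in replicates 3 and 4 (1.69 and 1.62, 1.32 and 1.38). These pairs are called array set 1 and array set 2 here. The poly-A spike-in control probe sets averaged 6.48 ± 0.68 (SD, n = 4) at P1, 5.99 ± 0.18 (SD, n = 4) at P12 and 5.28 ± 0.06 (SD, n = 3) at P28. This technical measure therefore also differed between the ages.

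**Figure D1:**
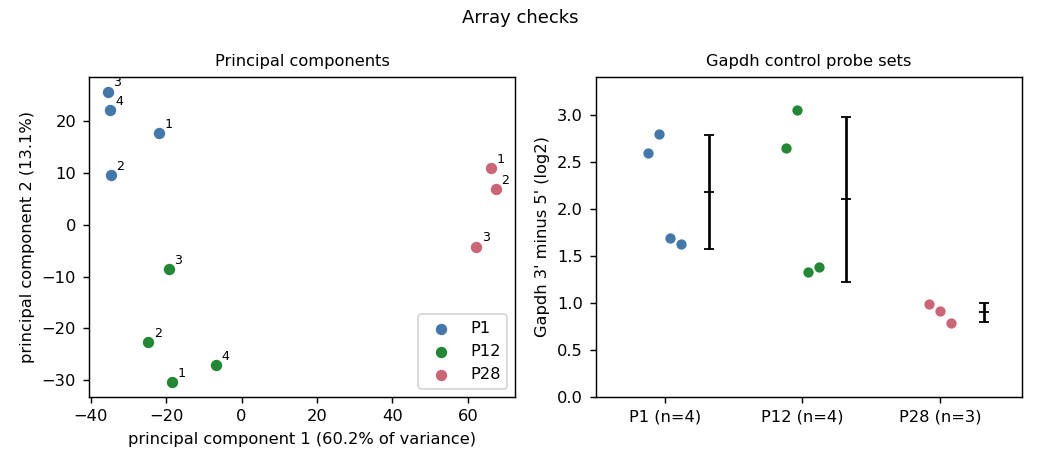
The left panel plots the first against the second principal component for each array (numbers are replicates), and the right panel plots the log2 difference of the Gapdh 3' and 5' control probe sets by age, with bars for mean and SD. The 3 P28 arrays stand apart on component 1 (60.2% of the variance) and had the lowest Gapdh differences, 0.79 to 0.99.

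Sex-linked genes differed between arrays. Xist, the RNA that coats the inactive X chromosome of females, was at 11.29 in P1 replicate 1 and at 5.82 to 5.96 in the other P1 arrays, and it was at 10.59 to 11.70 at P12 and 10.66 to 11.81 at P28. The Y-linked gene Kdm5d was at 5.76 in P1 replicate 1 and at 7.30 to 7.5 in the other P1 arrays. Another Y-linked gene, Eif2s3y, was at 7.93 and at 9.34 to 9.64 there. At P12 Kdm5d was at 6.28 to 6.72 and Eif2s3y at 8.49 to 8.79, above P1 replicate 1 and below the other P1 arrays. At P28 they were at 4.24 to 5.33 and 6.96 to 7.99. The labels do not give the sex of the animals. These values differed between the ages, so a difference of sex cannot be told apart from age in any comparison. Of the 4 sex-linked genes measured, 1 rose and 0 fell in P12 against P1 (1 rose and 1 fell adjusted over the list alone), 0 rose and 2 fell in P28 against P12 (the same counts adjusted over the list alone), and 1 rose and 3 fell in P28 against P1 (also the same counts). This list was not tested as a set.

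Pax3 itself, whose locus carries GFP, was at 8.29 ± 0.25 (SD, n = 4) at P1, 8.60 ± 0.19 (SD, n = 4) at P12 and 8.48 ± 0.36 (SD, n = 3) at P28, and no comparison passed (adjusted p = 0.324, 0.663 and 0.455). Pax7, the satellite cell transcription factor, was at 10.75, 10.78 and 10.72, and the myogenic factors Myf5 (10.49, 10.39 and 10.67) and Myod1 (10.03, 10.54 and 10.47) also did not pass in any comparison. The cell cycle inhibitors Cdkn1a (10.97, 10.97 and 10.72), Cdkn1b (9.49, 9.94 and 9.66) and Cdkn1c (12.83, 12.97 and 12.43) did not pass either. The same held for Spry1, an inhibitor of receptor tyrosine kinase signalling (10.61, 10.81 and 10.92). A second probe set of Pax3 rose by 0.79 in P28 against P12, and the same was true of second probe sets of Pax7 (0.69) and Cdkn1b (1.89). With the mean of a gene's probe sets, Pax3 changed by 0.36, 0.30 and 0.66 and Cdkn1b by 0.55, 0.80 and 1.35 in P12 against P1, P28 against P12 and P28 against P1, and all 6 values passed. Calls appeared for Cdkn1b in P12 against P1 with array set as a block (0.46) and without P1 replicate 1 (0.63). With the 3' to 5' covariate they appeared for Myf5 (0.66 and 0.59) and Spry1 (0.76 and 0.99) in P28 against P12 and P28 against P1. Cdkn1c passed in P28 against P12 without P12 replicate 3 (-0.72), and after quantile normalization in that comparison (-0.54) and in P28 against P1 (-0.63).

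Calcr, the calcitonin receptor of quiescent satellite cells, rose by 0.76 ± 0.16 from P1 to P12, by 0.59 ± 0.17 from P12 to P28 and by 1.35 ± 0.17 from P1 to P28. Without P12 replicate 1 (0.50) or P28 replicate 1 (0.44) the middle value no longer passed. Heyl, a Notch effector, rose by 1.08 ± 0.23 from P1 to P28 (adjusted p = 0.00218), with 0.65 and 0.43 for the steps between, which did not pass. The first step passed with the replicate number or the array set as a block (0.65 in each), with the 3' to 5' covariate (0.67) and without P1 replicate 1 (0.78), and the second step with the mean of its probe sets (0.61). Myog, which drives differentiation, rose by 0.90 ± 0.20 from P1 to P12 (0.77 without P12 replicate 4, which no longer passed) and was at 12.42 at P12 and 11.89 at P28. That decrease passed under 2 alternatives, without P12 replicate 3 (-0.68) and after quantile normalization (-0.52). The proliferation marker Mki67 rose by 0.92 ± 0.19 from P1 to P12 and fell by 1.33 ± 0.21 from P12 to P28, with -0.41 between P1 and P28, which passed under 1 alternative, quantile normalization (-0.68). The P28 values of these genes carry the limit that age, muscles and a possible batch coincide.

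**Figure D2:**
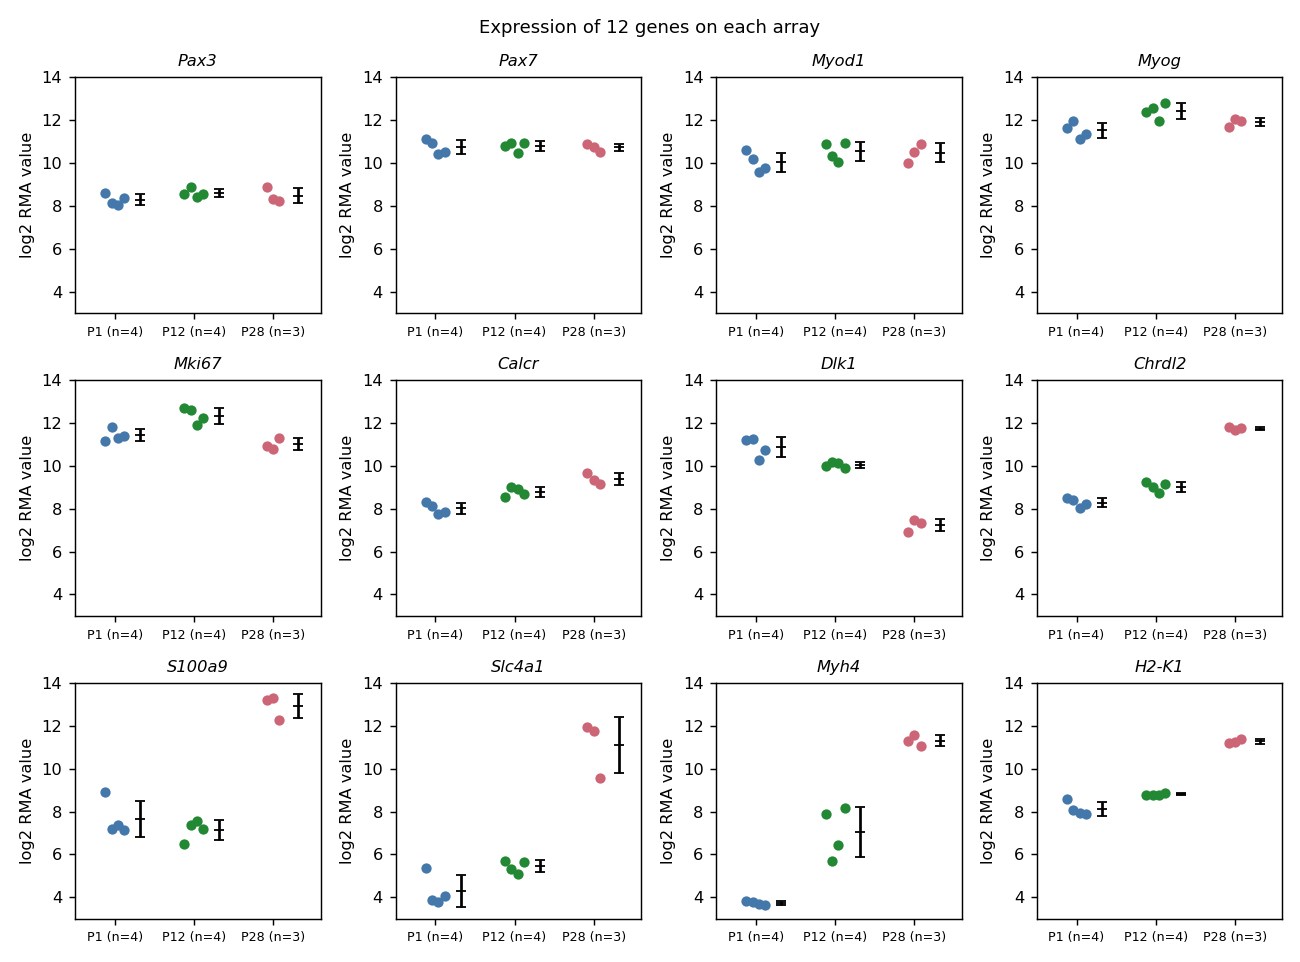
Log2 RMA values of 12 genes on each array, by age, with bars for mean and SD beside the points (n = 4 at P1 and P12, n = 3 at P28). Pax3 and Pax7 showed no change that passed, while Dlk1 fell and Chrdl2 rose at both steps.

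P12 was compared with P1 to see how these cells differ within the early ages, both labelled as proliferating and from trunk muscle. In camera with its preset correlation, genes of the cell cycle, the respiratory chain and sterol synthesis were higher at P12 (n = 4) than at P1 (n = 4), and imprinted growth genes, fetal RNA-binding genes and matrix genes were lower. With an estimated correlation none of these 6 calls was made (adjusted p = 0.126 to 0.45). The mean of the cell cycle list rose from 8.66 ± 0.30 to 9.38 ± 0.23 (SD, n = 4 each, exact permutation p = 0.0286, the smallest 4 against 4 can give, adjusted p = 0.0429). Adult fast fibre genes were among the largest increases, with the calcium buffer Pvalb up by 3.29 ± 0.26. The myosin Myh4 rose from 3.74 at P1, close to the background controls, to 7.06, so the size of its change is uncertain. Myh8, the perinatal myosin, fell by 1.93 ± 0.22.

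Of the 58 measured cell cycle genes, 28 rose and 1 fell (45 and 1 adjusted over the list alone, camera adjusted p = 5.12e-19, adjusted p = 0.273 with an estimated correlation). The number that rose was 18 without P1 replicate 3 or 4, 12 without P12 replicate 1, 13 without P12 replicate 4, 17 after quantile normalization, and 1 and 16 within array sets 1 and 2. Cyclin D1 (Ccnd1) rose by 1.65 ± 0.20, the mitotic survival factor Birc5 by 1.49 ± 0.29, the mitotic kinase Plk1 by 1.34 ± 0.23 and Racgap1 by 1.33 ± 0.23. Cyclin E1 (Ccne1), which acts at the entry into S phase, fell by 0.88 ± 0.18. With array set as a block, the mean change of the list was 0.72 (37 rose and 1 fell), and within array sets 1 and 2 it was 0.81 and 0.62. Among 17 cell cycle inhibitors and pocket proteins, 1 rose, Cdkn2c (1.05 ± 0.18), and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.000914 in the upward direction, adjusted p = 0.361 with an estimated correlation). With array set as a block 8 of them rose, and without P1 replicate 1 or 2 or P12 replicate 2 or 3 the number was 3, 2, 2 and 2.

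In the oxidative phosphorylation list, 12 of 45 genes rose and 0 fell (30 and 0 adjusted over the list alone, camera adjusted p = 3.17e-13, adjusted p = 0.297 with an estimated correlation), among them the cytochrome oxidase subunit Cox5a (0.82 ± 0.16) and the complex I subunit Ndufa9 (0.67 ± 0.14). Without P1 replicate 3 or 4 or P12 replicate 1 or 4, 2, 2, 3 and 2 of the list rose, and 19 without P12 replicate 3. In the cholesterol synthesis list, 5 of 20 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 1.44e-05, adjusted p = 0.389 with an estimated correlation). Without P1 replicate 1 the number that rose was 2, and it was 1 without P1 replicate 3 or 4 or P12 replicate 1 or 4. The sterol desaturase Sc5d rose by 1.12 ± 0.21. Idi1 rose by 0.90 ± 0.23, a call that ended without P12 replicate 4 (0.75) and without any of P1 replicates 1, 3 and 4 (0.81, 0.88 and 0.89) or P12 replicate 1 (0.81), after quantile normalization (0.72) and with the mean of its probe sets (0.82). The mean changes of the oxidative phosphorylation list within array sets 1 and 2 were 0.37 and 0.48, and those of the cholesterol list were 0.48 and 0.56.

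In the list of myogenic differentiation and fusion, 6 of 30 genes rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.389 with an estimated correlation). Lmod2, an actin filament nucleator of the sarcomere, rose by 2.86 ± 0.20, the fusion factor Mymk by 1.33 ± 0.19, the acetylcholine receptor subunit Chrna1 by 1.33 ± 0.16 and creatine kinase Ckb by 1.09 ± 0.15. Sarcomere genes moved both ways, with 8 of 41 up and 8 down (8 and 9 adjusted over the list alone), a mean of 0.14, a median of -0.12 and no call (camera adjusted p = 0.639). Of 29 myogenic progenitor and determination factors, 4 rose and 0 fell (4 and 1 adjusted over the list alone), also with no call (camera adjusted p = 0.267).

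Of 23 imprinted growth genes, 0 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.000188, adjusted p = 0.331 with an estimated correlation), including Peg10 (-1.67 ± 0.28) and Magel2 (-0.77 ± 0.13). Of 16 fetal RNA-binding and Lin28-let-7 axis genes, 0 rose and 2 fell, Hmga2 (-1.38 ± 0.17) and Igf2bp3 (-1.22 ± 0.18), with 0 and 4 adjusted over the list alone (camera adjusted p = 0.000513, adjusted p = 0.126 with an estimated correlation). Of 34 collagen and fibrillar matrix genes, 1 rose and 8 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.000847, adjusted p = 0.45 with an estimated correlation). Fibrillin 2 (Fbn2) fell by 1.92 ± 0.19, versican (Vcan) by 1.08 ± 0.22 and Mfap2 by 1.08 ± 0.16. The number of imprinted genes that fell was 3 without P1 replicate 2 or 4 or P12 replicate 1, and 2 without P12 replicate 4. For matrix genes it was 5 without P1 replicate 2 or P12 replicate 4 and 4 without P12 replicate 1. Within array sets 1 and 2 the mean changes were -0.30 and -0.25 for imprinted genes, -0.36 and -0.34 for fetal RNA-binding genes, and -0.32 and -0.20 for matrix genes.

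Of 18 circadian clock genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.39 with an estimated correlation). Dbp rose by 1.43 ± 0.27 and the repressor Nr1d1 by 1.27 ± 0.15. Of 34 immediate early and dissociation stress genes, 2 rose, Klf6 (0.85 ± 0.20) and Nr4a3 (0.61 ± 0.17), and 0 fell (the same counts adjusted over the list alone, camera adjusted p = 8.12e-05, adjusted p = 0.536 with an estimated correlation). With array set as a block or without P1 replicate 1, 10 stress genes rose, and 4 without P12 replicate 3. Without P1 replicate 1, 8 clock genes rose. The Klf6 call ended without P1 replicate 3 (0.75) or 4 (0.76) or P12 replicate 1 (0.71) or 2 (0.77), and the Nr4a3 call ended without any array except P1 replicate 1 and P12 replicate 3 (0.52 to 0.63), after quantile normalization (0.49) and with the mean of its probe sets (0.07). The mean changes of the clock list within array sets 1 and 2 were 0.32 and 0.50, and those of the stress list were 0.16 and 0.53.

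The estimated correlation ended all 17 calls of this comparison, and further alternatives ended the calls of the next 7 lists. Of 36 quiescent satellite cell genes, 6 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.00153, adjusted p = 0.536 with an estimated correlation). Asb5 rose by 2.57 ± 0.13 and Pdgfra, a receptor of mesenchymal cells, fell (-1.45 ± 0.28). The array means of that list were 9.71 ± 0.26 and 9.97 ± 0.16 (SD, n = 4 each, exact permutation p = 0.2, adjusted p = 0.2). That test takes no account of the array set. Within array set 1 the P1 arrays were at 9.86 and 9.98 and the P12 arrays at 10.09 and 10.10, and within array set 2 they were at 9.43 and 9.55 and at 9.74 and 9.95. The camera call held with array set as a block (adjusted p = 0.00241) and within array sets 1 and 2 (0.0479 and 0.00113). It ended without dim probe sets (adjusted p = 0.059) and after quantile normalization (0.14). Glycolysis genes (3 of 21 rose and 0 fell, 5 and 1 adjusted over the list alone) had camera adjusted p = 0.0206 and adjusted p = 0.446 with an estimated correlation, and Pfkp rose by 1.08 ± 0.17. Without P1 replicate 2 or P12 replicate 4 their adjusted p was 0.0514 and 0.0582, and it was 0.082 after quantile normalization, 0.107 without dim probe sets, and 0.1 and 0.015 within array sets 1 and 2. Ribosome biogenesis genes (2 of 33 rose and 0 fell, the same adjusted over the list alone), led by Polr1e (0.81 ± 0.15), had camera adjusted p = 0.00135 and adjusted p = 0.468 with an estimated correlation. That p was 0.319 after quantile normalization, 0.059 without dim probe sets, and 0.0704 and 0.000653 within array sets 1 and 2.

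Of 29 genes of MHC class I and the interferon response, 5 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.45 with an estimated correlation). Ifit2 rose by 0.92 ± 0.17 and Gbp3 by 0.83 ± 0.16. The adjusted p was 0.0618 without P1 replicate 2, 0.0517 without P12 replicate 4, 0.151 without dim probe sets, 0.053 with the mean of a gene's probe sets, and 0.112 and 0.00386 within array sets 1 and 2. Of 31 Wnt pathway genes, 1 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.0316, adjusted p = 0.468 with an estimated correlation). The adjusted p of the Wnt list was 0.0583 without P1 replicate 1, 0.0549 without P1 replicate 2, 0.104 without P12 replicate 4, 0.14 after quantile normalization, and 0.0688 and 0.0191 within array sets 1 and 2. Its 4 passing members, the antagonist Sfrp1 (-1.09 ± 0.27), Dkk3 (-0.53 ± 0.13), the receptor Fzd8 (-0.51 ± 0.13) and Wnt9a (0.48 ± 0.12), each lost their call without P12 replicate 4 (-0.96, -0.46, -0.49 and 0.46) and at least 1 of them also without each other array except P12 replicate 2.

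Few markers of other cell types passed between P1 and P12. Of 18 endothelial genes 0 rose and 0 fell (the same adjusted over the list alone), yet the list was called higher (mean 0.31, camera adjusted p = 0.0166, adjusted p = 0.597 with an estimated correlation). That adjusted p was 0.069 without P1 replicate 2, 0.054 without P1 replicate 3, 0.171 without P12 replicate 4, 0.143 without dim probe sets and 0.887 within array set 1 (mean 0.01), against 7.24e-06 within array set 2 (mean 0.61). Of 18 Schwann cell, neural and melanocyte genes 0 rose and 0 fell (the same adjusted over the list alone), and the list was called lower (mean -0.15, camera adjusted p = 0.021, adjusted p = 0.299 with an estimated correlation), with 0.112 after quantile normalization, 0.0601 without dim probe sets, and 0.0417 and 0.0613 within array sets 1 and 2. Of the 3 most abundant members of each of 8 lists of other cell types, only Acta2 passed (0.69 ± 0.17). Its call ended with the mean of its probe sets (0.39) and without any array except P1 replicate 2 and P12 replicate 3 (0.62 to 0.66). With array set as a block Ramp2 (0.39), Alas2 (0.76), Slc4a1 (1.16), Ednrb (-0.65), Notch3 (-0.43) and Lpl (0.66) passed, and without P1 replicate 1 Csf1r (-1.03), Slc4a1 (1.52) and Lpl (0.80). Slc4a1 and Lpl also passed with the replicate number as a block (1.16 and 0.66), Tagln after quantile normalization (-0.59), and Lpl under 5 more alternatives (0.66 to 0.80).

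The lists of leukocytes (1 of 22 rose, 1 fell, the same adjusted over the list alone), erythroid cells (1 of 8 rose, 0 fell, the same) and fibroblasts (1 of 17 rose, 2 fell, 2 and 3 adjusted over the list alone) were not called, with camera adjusted p of 0.0877, 0.222 and 0.121. The leukocyte list was called lower without P1 replicate 2 (0.0489), P12 replicate 3 (0.0468) or dim probe sets (0.0239), and the erythroid list was called higher within array set 2 (0.0291). Nor were those of pericytes and smooth muscle (3 of 15 rose, 1 fell, the same adjusted over the list alone) and adipocytes (1 of 12 rose, 1 fell, 2 and 1 adjusted over the list alone), with 0.556 and 0.861. Of 15 tendon and cartilage genes 0 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.0598), which became a call with the replicate number as a block (0.0475), without dim probe sets (0.0294) and without P1 replicate 4 (0.0449) or P12 replicate 2 (0.0168) or 3 (0.0418). No call was made for Notch (1 of 24 rose, 0 fell, the same adjusted over the list alone), TGF-beta and BMP (3 of 34 rose, 2 fell, the same) and basement membrane genes (1 of 27 rose, 2 fell, 2 and 3 adjusted over the list alone), with 0.429, 0.973 and 0.378. The lists of fatty acid oxidation (2 of 26 rose, 0 fell, 3 and 0 adjusted over the list alone), hormone-responsive genes (3 of 21 rose, 1 fell, the same adjusted over the list alone) and Hox and regional patterning genes (3 of 38 rose, 0 fell, the same) had 0.664, 0.695 and 0.553. The mean of the hormone-responsive list was 0.01 and its median -0.09.

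The 10 largest increases also held Pcolce2, an enhancer of procollagen processing (3.54 ± 0.19), the sorting receptor Sorl1 (2.45 ± 0.20), the ephrin receptor Ephb1 (2.29 ± 0.18), the oestrogen receptor Esr1 (2.20 ± 0.19), Gpr50 (2.10 ± 0.29) and the erythroid gene Hemgn. Hemgn was at 2.74 at P1, under the background controls, and at 4.76 at P12, so the size of its change is uncertain. Its call ended without P1 replicate 2, 3 or 4 or P12 replicate 1 or 4 and with eBayes trend and robust options. The 10 largest decreases held the microtubule protein Dcx (-2.46 ± 0.28), the kinase Stk26 (-2.27 ± 0.29), the mast cell proteases Cma1 (-2.06 ± 0.20) and Cpa3 (-2.03 ± 0.19), Ccn3 (-2.05 ± 0.35), the inositol transporter Slc2a13 (-2.0 ± 0.18), the angiotensin receptor Agtr2 (-1.93 ± 0.26) and Col17a1 (-1.89 ± 0.17).

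In all, 1195 of 18193 genes (6.57%) changed from P1 to P12 in the limma test, 824 up and 371 down, and 270 of them by at least 2-fold. All arrays of 1 age lay above all of the other in 11.9% of genes, against 2.86% by chance. After a further quantile normalization 577 rose and 617 fell, so the excess of increases turned around. With array set as a block 2163 genes changed (1531 up and 632 down), and 128 and 907 changed within array sets 1 and 2. Without P1 replicate 3 or 4 or P12 replicate 1 or 4 the count was 678, 646, 655 and 639. In 11 of the 15 called lists with members that passed, their number in the direction of the list moved by over 1.5 times without at least 1 array. This happened in 9 lists without P12 replicate 1, 8 without P12 replicate 4, 7 without P1 replicate 4 and 6 without P1 replicate 3. Of the 31 lists 17 were called, 12 up and 5 down, and 0 with an estimated correlation. Regroupings of the 8 arrays gave as many list calls in 2 of 35 splits, so chance was not excluded for their number. These splits took no account of the array set.

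P28 was compared with P12 for the step that the series describes as leading from proliferating to quiescent satellite cells. At P28 (n = 3) cell cycle genes and imprinted growth genes were lower than at P12 (n = 4). Quiescent satellite cell genes, sarcomere genes, and markers of leukocytes, erythroid cells, endothelium and fibroblasts were higher. These were camera calls with the preset correlation, and 0 lists were called with an estimated one. The cell cycle list fell from 9.38 ± 0.23 (SD, n = 4) to 8.21 ± 0.28 (SD, n = 3), and the quiescent list rose from 9.97 ± 0.16 to 10.51 ± 0.12 (exact permutation p = 0.0286 for each, the smallest possible, adjusted p = 0.0429). Age, muscles and a possible batch coincide in this step, and sex-linked genes differed as well. The 3' bias of the RNA was lower in the same arrays and markers of other cell types were higher, beside each gene group described for it.

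**Figure D3:**
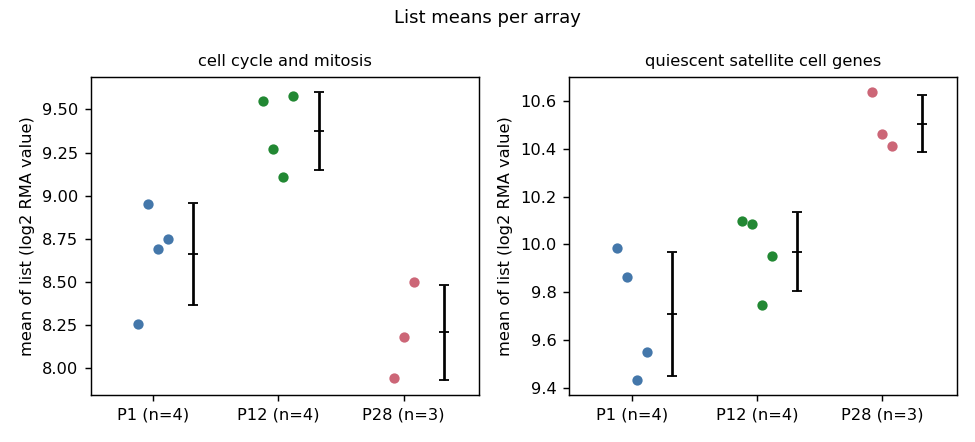
Mean log2 RMA value of the measured members of the cell cycle list (58 genes) and the quiescent satellite cell list (36 genes) on each array, by age, with bars for mean and SD (n = 4 at P1 and P12, n = 3 at P28). The cell cycle mean was highest at P12 (9.38), and the quiescent mean was highest at P28 (10.51), where age, muscles and a possible batch coincide.

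Of 58 cell cycle genes, 0 rose and 53 fell (0 and 55 adjusted over the list alone, camera adjusted p = 3.94e-19, adjusted p = 0.273 with an estimated correlation). The mitotic kinesin Kif2c fell by 2.43 ± 0.32, Ccne1 by 2.13 ± 0.19, Ect2, a factor of cell division, by 1.85 ± 0.29 and the mitotic regulator Cdc20 by 1.77 ± 0.28. Of the 28 cell cycle genes that rose from P1 to P12, 24 then fell. The list of cell cycle inhibitors was not called, with 4 of 17 up and 4 down (the same adjusted over the list alone, camera adjusted p = 0.553).

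Of 36 quiescent satellite cell genes, 12 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.00247, adjusted p = 0.541 with an estimated correlation). The median change of the list (0.17) was below its mean (0.54). Lists called higher here share members with the quiescent list, among them Tek (endothelial), Pdgfra and Cd34 (fibroblast), Rgs5 and Notch3 (pericyte) and Bmp6 (TGF-beta). The chordin-like protein Chrdl2 rose by 2.71 ± 0.15, Asb5 by 2.28 ± 0.14, the secreted peroxidase Gpx3 by 2.23 ± 0.24 and Bmp6 by 2.19 ± 0.23. The transcription factor Sox8 fell by 1.49 ± 0.24. Megf10, a receptor of satellite cells, fell by 0.72 ± 0.22, a call that ended without P12 replicate 1 (-0.64) or 2 (-0.62) or P28 replicate 3 (-0.55) and with the 3' to 5' covariate (-0.19). Myogenic progenitor and determination factors moved both ways, 5 of 29 up and 8 down (the same adjusted over the list alone, camera adjusted p = 0.343).

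Imprinted growth genes fell further, with 0 of 23 up and 12 down (1 and 13 adjusted over the list alone, camera adjusted p = 1.38e-05, adjusted p = 0.273 with an estimated correlation). Neuronatin (Nnat) fell by 3.54 ± 0.19, Peg10 fell by 3.02 ± 0.30, the Notch ligand-like protein Dlk1 by 2.80 ± 0.21 and Usp29 by 1.73 ± 0.17. The fetal RNA-binding list, with 1 of 16 up and 4 down (the same adjusted over the list alone), was not called (camera adjusted p = 0.323). The kinase gene Nrk had the largest decrease (-4.12 ± 0.19), followed by Agtr2 (-3.60 ± 0.28). The other genes among the 10 largest decreases were Npas3 (-2.45 ± 0.23), Rad51ap1 (-2.43 ± 0.24), Shcbp1 (-2.27 ± 0.25) and Ccdc141 (-2.27 ± 0.29).

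Of 41 sarcomere genes, 30 rose and 2 fell (32 and 4 adjusted over the list alone, camera adjusted p = 2.6e-12, adjusted p = 0.216 with an estimated correlation). Pvalb rose by 4.40 ± 0.29, Myh4 by 4.25 ± 0.43 and the fast fibre actinin Actn3 by 3.68 ± 0.21. The 2 that fell were the perinatal and embryonic myosins Myh8 (-1.64 ± 0.23) and Myh3 (-1.32 ± 0.20). Of 30 genes of myogenic differentiation and fusion, 15 rose and 3 fell (18 and 5 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.389 with an estimated correlation). Muscle creatine kinase (Ckm) rose by 3.96 ± 0.33 and desmin (Des) by 1.61 ± 0.15, while the fusion peptide Mymx fell by 1.35 ± 0.23 and Vgll2 by 1.08 ± 0.17.

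Of 21 glycolysis genes, 13 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 1.28e-07, adjusted p = 0.195 with an estimated correlation), led by the muscle isoforms Pgam2 (3.07 ± 0.33) and Eno3 (2.96 ± 0.29). Of 26 genes of fatty acid uptake and oxidation, 13 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 5.11e-05, adjusted p = 0.273 with an estimated correlation), led by the fatty acid carrier Cd36 (3.46 ± 0.23) and Fabp3 (2.49 ± 0.29). The oxidative phosphorylation list was not called (7 of 45 up, 1 down, 6 and 0 adjusted over the list alone, camera adjusted p = 0.319). Nor were the cholesterol list (2 of 20 up, 1 down, the same adjusted over the list alone, 0.909) and the ribosome biogenesis list (3 of 33 up, 3 down, the same, 0.798), whose means (0.02 and 0.06) and medians (-0.02 each) differ in sign.

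Of 29 genes of MHC class I and the interferon response, 24 rose and 0 fell (27 and 0 adjusted over the list alone, camera adjusted p = 6.1e-17, adjusted p = 0.126 with an estimated correlation). Ifit1 rose by 3.0 ± 0.24, the class I heavy chain H2-K1 by 2.47 ± 0.16 and Gbp2 by 2.37 ± 0.14. H2-D1 rose by 2.45 ± 0.17 on its brightest probe set and fell on 2 others (-2.29 and -1.64), and with the mean of its probe sets it no longer passed (0.70). Of 34 immediate early and dissociation stress genes, 18 rose and 0 fell (19 and 1 adjusted over the list alone, camera adjusted p = 9.99e-07, adjusted p = 0.446 with an estimated correlation). Ccn2 rose by 2.90 ± 0.39 and Klf2 by 2.69 ± 0.21. Of 21 glucocorticoid and thyroid hormone responsive genes, 11 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.000153, adjusted p = 0.371 with an estimated correlation). Sgk1 rose by 2.66 ± 0.22 and Hr by 2.42 ± 0.21.

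Of 18 clock genes, 9 rose and 2 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.517 with an estimated correlation). Nr1d1 rose by 3.27 ± 0.17 and Hlf fell (-1.45 ± 0.20). The adjusted p was 0.0524 without P12 replicate 4 and 0.0753 without dim probe sets. Of 34 TGF-beta and BMP genes, 13 rose and 5 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.0363, adjusted p = 0.61 with an estimated correlation). Bmp5 rose by 2.18 ± 0.22 and Tgfb2 fell (-0.92 ± 0.18). The adjusted p of the TGF-beta and BMP list was 0.0539 without P12 replicate 1, 0.0524 without P12 replicate 4, 0.0583 without P28 replicate 3, 0.0729 after quantile normalization and 0.0607 with the replicate number as a block. Of 38 Hox and regional patterning genes, 2 rose, Hoxc10 (1.40 ± 0.22) and Tbx4 (1.18 ± 0.16), and 8 fell, led by Hoxb5 (-1.34 ± 0.19), with the same counts adjusted over the list alone (camera adjusted p = 0.0469, adjusted p = 0.291 with an estimated correlation). Without P12 replicate 1 or 3 or P28 replicate 1 or 3 that list had adjusted p of 0.0716, 0.08, 0.0654 and 0.0967. Without P12 replicate 2 the number that fell was 5. The list had 0.0746 after quantile normalization, 0.0658 without dim probe sets and 0.0522 with the mean of a gene's probe sets.

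Of 34 collagen and fibrillar matrix genes, 17 rose and 4 fell (18 and 4 adjusted over the list alone, camera adjusted p = 6.4e-05, adjusted p = 0.389 with an estimated correlation). Decorin (Dcn) rose by 2.39 ± 0.20 and tenascin C (Tnc) fell (-1.62 ± 0.27). The lists of basement membrane (7 of 27 up, 4 down, the same adjusted over the list alone), Notch (3 of 24 up, 4 down, the same) and Wnt genes (4 of 31 up, 6 down, 5 and 7 adjusted over the list alone) were not called, with camera adjusted p of 0.664, 0.837 and 0.876. The mean of the basement membrane list was 0.04 and its median -0.05.

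Markers of several other cell types were higher, and the 3 most abundant members of each list over all arrays are given with them. Of 22 leukocyte genes, 17 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 1.19e-11, adjusted p = 0.126 with an estimated correlation), and the neutrophil proteins S100a9 and S100a8 rose by 5.78 ± 0.38 and 5.53 ± 0.45 to 12.92 and 12.59. Csf1r (8.84 and 9.54) did not pass, except with the mean of its probe sets (0.80), with the replicate number as a block (0.75) and without P28 replicate 1 (1.09). Laptm5 rose by 1.18 ± 0.32 to 10.14, a call that ended without P28 replicate 2 (0.99) or 3 (1.04) and with the 3' to 5' covariate (1.19). Of 8 erythroid genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 5.11e-05, adjusted p = 0.291 with an estimated correlation). The band 3 anion exchanger Slc4a1 rose by 5.65 ± 0.47 to 11.10 and Alas2 by 2.76 ± 0.42 to 9.87. Slc4a1 (9.58, others 11.97 and 11.74) and Hemgn (7.66, others 10.33 and 10.15) were lower on P28 replicate 3 than on the other P28 arrays. The SD of the erythroid list mean over arrays was 0.863 at P28 and 0.095 at P12. Add2 (5.65 and 6.17, adjusted p = 0.0526) did not pass, except under 5 alternatives, among them leaving out P12 replicate 1 (0.65) or P28 replicate 3 (0.70). Of 18 endothelial genes, 16 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 5.88e-13, adjusted p = 0.216 with an estimated correlation). Cdh5 rose by 2.58 ± 0.33 to 8.86 and of the most abundant members Ramp2 by 1.53 ± 0.18 to 10.06 and Kdr by 1.64 ± 0.22 to 9.25, while Egfl7 (7.68 and 7.88) did not pass. Of 17 fibro-adipogenic and fibroblast genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 1.43e-07, adjusted p = 0.23 with an estimated correlation). Thy1 rose by 3.07 ± 0.29 to 10.55. Gelsolin (Gsn) rose by 1.26 ± 0.26 to 12.28, though a dimmer probe set of it fell (-0.78). Dpt (11.24 and 11.72) did not pass, except with the replicate number as a block (0.45), after quantile normalization (0.46), with the 3' to 5' covariate (0.88) and without P28 replicate 3 (0.66). Col15a1 fell by 0.83 ± 0.29, a call that ended without P12 replicate 1 (-0.71) or 2 (-0.62) or P28 replicate 2 (-0.72) or 3 (-0.81) and with eBayes trend and robust options (-0.83). With the 3' to 5' covariate, which is extrapolated to P28, its estimate was 0.005.

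Of 15 pericyte and smooth muscle genes, 9 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 5.11e-05, adjusted p = 0.273 with an estimated correlation). Myh11 rose by 2.03 ± 0.25, and of the most abundant members Tagln by 1.37 ± 0.20 to 10.68. Acta2 (12.88 and 12.57) and Notch3 (10.24 and 10.59) did not pass, except Acta2 without P12 replicate 3 (-0.47) and Notch3 with the 3' to 5' covariate (1.0). Of 15 tendon and cartilage genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.216 with an estimated correlation). Cilp rose by 3.35 ± 0.25. Of the most abundant members Fmod rose by 1.79 ± 0.18 to 10.09 and Sox9 by 0.67 ± 0.24 to 9.98. The Sox9 call ended with the replicate number as a block (0.56) and without P12 replicate 1, 3 or 4 (0.68, 0.61 and 0.52) or P28 replicate 2 or 3 (0.76 and 0.43). Egr1 (13.44 and 12.98) passed with the replicate number as a block (-0.49), after quantile normalization (-0.50) and without P12 replicate 3 (-0.61) but not otherwise. Of 12 adipocyte genes, 6 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.00134, adjusted p = 0.195 with an estimated correlation). Scd1 rose by 3.70 ± 0.29 and of the most abundant members Car3 by 2.69 ± 0.25 to 12.82 and Fabp4 by 2.29 ± 0.27 to 12.32, while Lpl (11.60 and 11.47) did not pass. The Schwann cell, neural and melanocyte list was not called (2 of 18 up, 1 down, the same adjusted over the list alone, camera adjusted p = 0.411), although Ednrb rose by 1.95 ± 0.26 to 8.41. Cnp (9.77 and 9.59) and Mbp (8.96 and 8.26) passed under 1 alternative, without P28 replicate 2 (-0.55 and -1.14), while 2 dimmer probe sets of Mbp rose (0.89 and 3.21). The remaining genes among the 10 largest increases were the neutrophil granule genes Ngp (4.89 ± 0.45), Lcn2 (4.81 ± 0.51), Camp (4.59 ± 0.41) and Mpo (4.33 ± 0.49), the erythroid gene Hemgn (4.62 ± 0.52) and the extracellular superoxide dismutase Sod3 (4.49 ± 0.30).

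**Figure D4:**
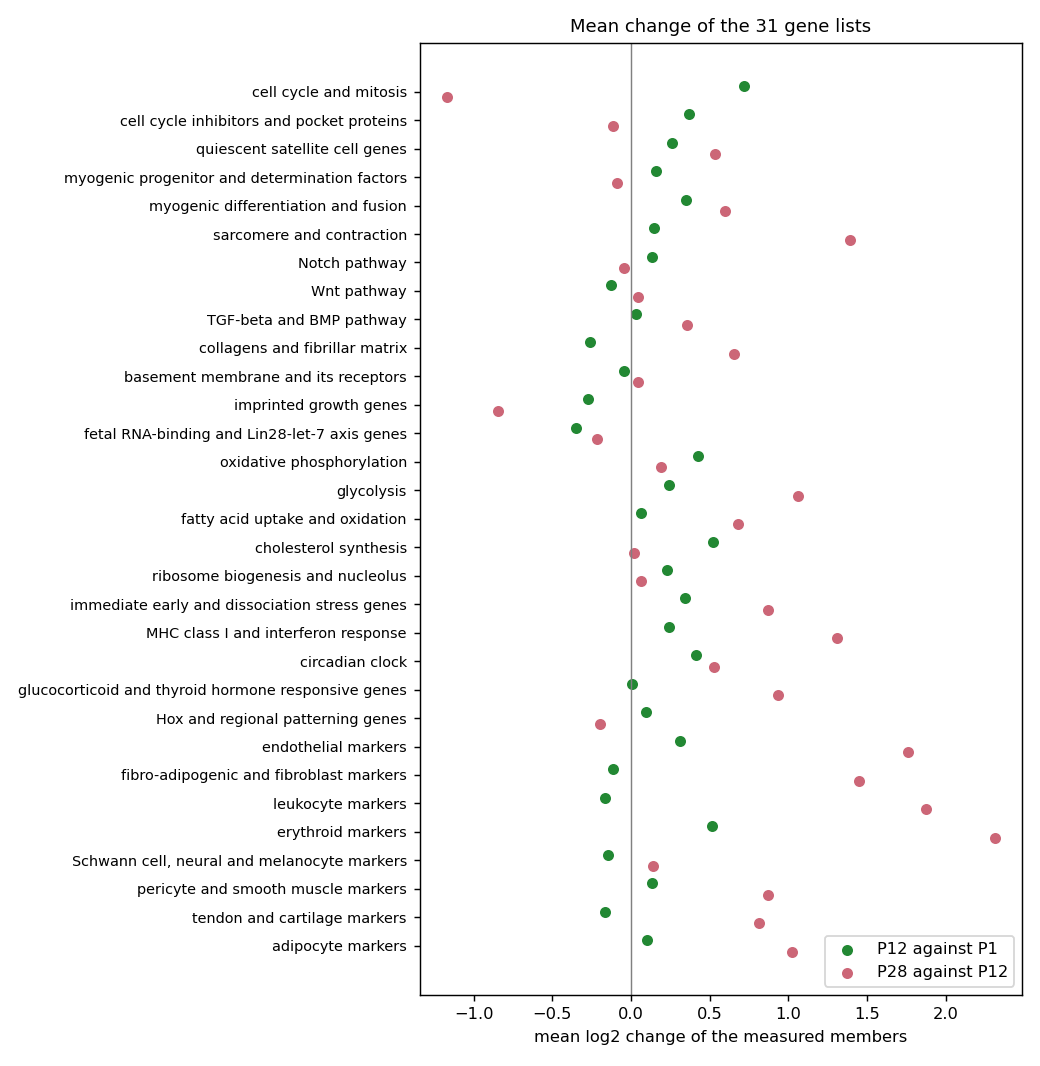
Mean log2 change of the measured members of each of the 31 gene lists, in P12 against P1 (green) and in P28 against P12 (red). The cell cycle list moved from 0.72 in the first step to -1.17 in the second, and the erythroid (2.31), leukocyte (1.88) and endothelial (1.76) lists had the largest increases of the second step, in which age, muscles and a possible batch coincide.

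In the limma test 5716 genes (31.4%) changed from P12 to P28, 2860 up and 2856 down, and 1710 of them by at least 2-fold. With the 3' to 5' covariate, which is extrapolated to P28, 2575 rose and 1575 fell. The arrays of the 2 ages did not overlap in 36.9% of genes, against 5.71% by chance. Of the 31 lists 21 were called, 18 up and 3 down, and 0 with an estimated correlation. Regroupings of the 7 arrays gave as many list calls in 2 of 35 splits, so chance was not excluded for the number of lists.

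P28 was compared with P1 for the whole span of ages, with the same limit on P28. Fast fibre genes were among the largest increases, Pvalb by 7.69 ± 0.29 and Myh4 (from 3.74 at P1, close to the background controls, to 11.30), with the erythroid genes Slc4a1 (6.81 ± 0.47) and Hemgn (from 2.74, under those controls, to 9.38), the neuropeptide galanin (Gal, 5.32 ± 0.19), the AP-1 factor Fosl1 (5.28 ± 0.34), Pcolce2 (5.27 ± 0.21), S100a9 (5.27 ± 0.38), Myhas (5.25 ± 0.26) and Lmod2 (5.19 ± 0.22). The largest decreases were those of Agtr2 (-5.53 ± 0.28), Nrk (-4.92 ± 0.19), Peg10 (-4.69 ± 0.30), Dcx (-4.12 ± 0.30), Nnat (-3.80 ± 0.19), Dlk1 (-3.63 ± 0.21), Stk26 (-3.59 ± 0.31), Myh8 (-3.57 ± 0.23), Fbn2 (-3.54 ± 0.21) and Arfgef3, which ended at the level of the background controls (6.85 and 3.53). The sizes and ranks of the Myh4, Hemgn and Arfgef3 changes are therefore uncertain. Cell cycle genes were lower at P28 than at P1 in camera but not in the test of array means. Quiescent genes, sarcomere genes and the markers of 7 other cell types were higher in camera, and the Schwann cell, neural and melanocyte list was not called. With an estimated correlation 0 lists were called.

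Of 58 cell cycle genes, 3 rose and 24 fell (3 and 29 adjusted over the list alone, camera adjusted p = 3.79e-05, adjusted p = 0.536 with an estimated correlation). The number that fell was 12 without P1 replicate 2 or P28 replicate 2, 14 without P1 replicate 4, 15 without P28 replicate 1, 8 with the 3' to 5' covariate and 37 after quantile normalization. Ccne1 fell (-3.01 ± 0.19) and Ccnd1 rose (1.73 ± 0.22). The array means of the cell cycle list were 8.66 ± 0.30 (SD, n = 4) and 8.21 ± 0.28 (SD, n = 3, exact permutation p = 0.114, adjusted p = 0.137). Of 36 quiescent satellite cell genes, 14 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 7.51e-05, adjusted p = 0.446 with an estimated correlation). The median change of the list (0.33) was below its mean (0.80). Asb5 rose by 4.85 ± 0.14 and Sdc4 by 2.49 ± 0.16. The array means of the quiescent list were 9.71 ± 0.26 (SD, n = 4) and 10.51 ± 0.12 (SD, n = 3, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0429). Of 23 imprinted genes, 0 rose and 13 fell (the same adjusted over the list alone, camera adjusted p = 6.6e-07, adjusted p = 0.273 with an estimated correlation), and of 16 fetal RNA-binding genes, 0 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.00388, adjusted p = 0.195 with an estimated correlation). Plag1 fell to 3.30, under the background controls, from 5.28.

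Of 41 sarcomere genes, 25 rose and 4 fell (25 and 5 adjusted over the list alone, camera adjusted p = 5.67e-08, adjusted p = 0.273 with an estimated correlation), and of 30 differentiation genes, 21 rose and 4 fell (22 and 4 adjusted over the list alone, camera adjusted p = 1.15e-05, adjusted p = 0.273 with an estimated correlation). Of 45 oxidative phosphorylation genes, 24 rose and 0 fell (30 and 0 adjusted over the list alone, camera adjusted p = 3.75e-07, adjusted p = 0.446 with an estimated correlation), led by the muscle isoforms Cox7a1 (3.52 ± 0.36) and Cox8b (2.77 ± 0.19). For glycolysis 16 of 21 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 1.8e-08, adjusted p = 0.195 with an estimated correlation), and for fatty acid oxidation 16 of 26 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 5.11e-05, adjusted p = 0.273 with an estimated correlation). For cholesterol synthesis 9 of 20 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.597 with an estimated correlation), led by Msmo1 (2.13 ± 0.39). This call ended without P28 replicate 3 (adjusted p = 0.109), after quantile normalization (0.0807), without dim probe sets (0.0677) and with the 3' to 5' covariate (0.0638).

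For MHC class I and the interferon response 28 of 29 genes rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 6.1e-17, adjusted p = 0.126 with an estimated correlation). H2-K1 rose by 3.16 ± 0.16. For stress genes 25 of 34 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 2.74e-09, adjusted p = 0.389 with an estimated correlation). For clock genes 9 of 18 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.000914, adjusted p = 0.389 with an estimated correlation). Nr1d1 rose by 4.54 ± 0.17. For hormone-responsive genes 11 of 21 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.00306, adjusted p = 0.446 with an estimated correlation). Sgk1 rose by 3.76 ± 0.22. For collagens and matrix 15 of 34 rose and 4 fell (15 and 5 adjusted over the list alone, camera adjusted p = 0.0206, adjusted p = 0.606 with an estimated correlation), a call that ended without P28 replicate 1 (adjusted p = 0.0933), after quantile normalization (0.141) and without dim probe sets (0.119).

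Among other cell types, 17 of 18 endothelial genes rose and 0 fell (18 and 0 adjusted over the list alone, camera adjusted p = 7.3e-13, adjusted p = 0.216 with an estimated correlation), and 15 of 22 leukocyte genes rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 1.12e-07, adjusted p = 0.195 with an estimated correlation). The erythroid list had 7 of 8 up and 0 down (the same adjusted over the list alone, camera adjusted p = 0.000125, adjusted p = 0.301 with an estimated correlation), and the fibroblast list 12 of 17 up and 1 down (12 and 2 adjusted over the list alone, camera adjusted p = 1.15e-05, adjusted p = 0.273 with an estimated correlation). Pericyte genes had 11 of 15 up and 1 down (the same adjusted over the list alone, camera adjusted p = 7.51e-05, adjusted p = 0.273 with an estimated correlation), and adipocyte genes 6 of 12 up and 1 down (8 and 1 adjusted over the list alone, camera adjusted p = 0.00377, adjusted p = 0.216 with an estimated correlation). Tendon genes had 8 of 15 up and 0 down (the same adjusted over the list alone, camera adjusted p = 0.0194, adjusted p = 0.297 with an estimated correlation), a call that ended without dim probe sets (adjusted p = 0.0718).

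No call was made for cell cycle inhibitors (6 of 17 up, 3 down, 6 and 4 adjusted over the list alone, camera adjusted p = 0.434, but 0.023 with 9 up and 2 down with the mean of a gene's probe sets), progenitor factors (5 of 29 up, 7 down, the same adjusted over the list alone, 0.751), Notch (6 of 24 up, 2 down, the same, 0.798) or Wnt (5 of 31 up, 10 down, the same, 0.378). Nor was one made for TGF-beta and BMP (14 of 34 up, 6 down, 14 and 8 adjusted over the list alone, 0.0618), basement membrane (4 of 27 up, 5 down, the same adjusted over the list alone, 0.909), ribosome biogenesis (12 of 33 up, 1 down, the same, 0.0618), Hox genes (4 of 38 up, 11 down, 4 and 12 adjusted over the list alone, 0.125) or Schwann cells (3 of 18 up, 1 down, the same adjusted over the list alone, 0.837). Mean and median differ in sign for progenitor factors (0.07 and -0.03) and Notch (0.09 and -0.04). The TGF-beta list became a call with the 3' to 5' covariate (0.0131) and without P1 replicate 1 (0.0231) or P28 replicate 2 (0.026). The ribosome biogenesis list became one with the replicate number as a block (0.0394), with the mean of a gene's probe sets (0.0276) and without P1 replicate 1 (0.0482) or P28 replicate 1 (0.0331) or 2 (0.0201).

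In the limma test 6656 genes (36.6%) changed from P1 to P28, 3664 up and 2992 down, and 2024 of them by at least 2-fold. After quantile normalization 3278 rose and 3945 fell, so the excess of increases turned around here too. With the 3' to 5' covariate, which is extrapolated to P28, 3464 rose and 1725 fell. Arrays did not overlap in 41.6% of genes, against 5.71% by chance. Of the 31 lists 22 were called, 19 up and 3 down, and 0 with an estimated correlation. Regroupings gave as many list calls in 3 of 35 splits, so chance was not excluded for their number. In the moderated F test over the 3 ages 7098 genes (39.0%) differed.

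The successive steps were compared gene by gene to see which changes went on and which turned back. From P1 to P12 and again from P12 to P28, 220 genes rose in both steps and 88 fell in both. Another 224 genes rose and then fell, and 115 fell and then rose. Asb5, Chrdl2, Nr1d1, Pvalb and Myh4 rose in both steps, and Agtr2, Peg10, Dlk1, Myh8 and Fbn2 fell in both. The cell cycle genes Birc5, Plk1 and Racgap1 rose and then changed by -1.09, -1.10 and -1.38, which passed, and Bmp6 fell and then rose. The Dlk1 call of the first step ended without P1 replicate 2 (-0.70) or P12 replicate 1 (-0.81) or 4 (-0.78).

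Independent lists of the same sizes would share 130 and 58.2 genes in the same directions and 129 and 58.3 in opposite ones. Because both steps use the P12 arrays, chance changes oppose each other, and in 100 simulations of unchanged groups the log2 changes had a mean correlation over genes of -0.463, against 0.00187 in the data, with a mean of 0 genes called in both steps. The simulations held no changed genes, so that 0 was fixed beforehand. It does not tell how many genes steps with real changes would share. With separate P12 arrays for each step, over the 6 ways to divide them, 55 to 413 genes changed in the same direction and 49 to 211 in opposite ones. Without P1 replicate 3 or 4 or P12 replicate 1 or 4, 187, 173, 172 and 172 genes changed in the same direction and 208, 193, 165 and 197 in opposite ones. Genes are not independent replicates, and the second step carries the limit on P28 given above.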

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

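The tests of the 3 patterns weighed here were chosen after the results were seen, while the search for single arrays far from their group and the tests of probe sets without a single gene symbol followed fixed rules.

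In 454 groups of 4 arrays, 1 array of P1 or P12 lay far from the other 3 in 33 groups, where chance gives about 22.7, or 1 in 20 groups. In 20 of the 33 that array was P1 replicate 1. It was high for Xist (11.29, others 5.82 to 5.96) and low for Kdm5d (5.76, others 7.30 to 7.5). It was high for the neutrophil genes S100a9 (8.89, others 7.15 to 7.38), S100a8 (9.05, others 7.30 to 7.38), Ngp (7.94, others 5.90 to 6.08), Lcn2 (6.12, others 3.80 to 3.98), Camp (7.42, others 5.64 to 5.92) and Mpo (6.42, others 3.98 to 4.2). The erythroid genes Hemgn (3.93, others 2.19 to 2.44) and Slc4a1 (5.39, others 3.80 to 4.07) were high as well. So were Zbtb16 (8.16, others 5.90 to 6.20), Mt1 (11.30, others 10.54 to 10.67), Id3 (10.57, others 9.77 to 9.90), Scd1 (7.10, others 6.07 to 6.18) and Tbx2 (5.28, others 4.27 to 4.44). It was low for the cell cycle genes Birc5 (6.93, others 8.01 to 8.17) and Ccnf (6.33, others 7.0 to 7.04), and for Ifit2 (6.82, others 7.56 to 7.68), Csf1r (8.55, others 9.86 to 9.88) and Atp5g1 (9.87, others 10.22 to 10.28).

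P1 replicate 2 stood apart for Fbn2 (9.68), Hoxa4 (5.08), Emcn (4.54) and Retn (6.05), and P1 replicate 4 for Nr1d1 (5.64). P12 replicate 1 stood apart for Asb5 (8.41, others 8.71 to 8.76) and Csf1r (8.88, others 8.83). P12 replicate 3 stood apart for Hmga2 (4.82, others 4.66 to 4.68), Acta2 (12.40, others 12.97 to 13.08) and Atf3 (10.08, others 10.31 to 10.34). P12 replicate 4 stood apart for Racgap1 (9.66, others 9.1 to 9.19), H2-K1 (8.88, others 8.78 to 8.79) and Cox6a2 (9.19, others 8.73 to 8.79). Of 10092 probe sets with no symbol or several, which no comparison of genes used, 211 changed in P12 against P1, 2233 in P28 against P12 and 2775 in P28 against P1.

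Leukocyte, endothelial and erythroid markers were higher at P28 than at P12, although the sort kept GFP-positive cells. Of the 48 measured members 39 rose, S100a9 (to 12.92) and Slc4a1 (to 11.10) included, but this count restates the pattern and lends no support to RNA of such cells in the P28 sorts; 31 of the 48 were above the median of all probe sets (5.54) at P1 and P12 already, and 1 stands in another list. A lower share of satellite cells that raised endothelial and Schwann cell types alike is argued against only weakly. The endothelial median change exceeded the Schwann cell one by 1.62 (bootstrap SE 0.24 over genes, not arrays). Both changes had been seen before, the Schwann cell list was dim (mean 5.62 at P12), and no other cell types were compared here. Random lists of matched brightness had medians up to 0.36, with the 3 lists at percentile 100. As these 3 were picked for their rise, processing that moves genes by brightness stays open. RNA of such cells, age, the muscles dissected and a batch of sorts or arrays stay open and cannot be told apart by this design.

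Cell cycle genes were higher at P12 than at P1. A difference in 3' bias of the RNA between arrays is argued against as the whole cause, because the list's mean change was 0.71 with that bias as a covariate (camera adjusted p = 7.36e-16, from 9.83e-21 to 0.433 over all alternatives, the highest with estimated correlations) and 0.72 without it. The bias itself was 2.18 ± 0.61 at P1 and 2.10 ± 0.88 at P12 (SD, n = 4 each), so the covariate could move this change little. For a difference of sex, P1 replicate 1, the only P1 array with high Xist, would lie nearer to P12 than the other P1 arrays, but its list mean of 8.25 was below the lowest of them (8.69), and without it the change was 0.58. That value goes against sex, yet a single array decides nothing, and the P12 arrays, high in Xist, had higher Kdm5d (6.28 to 6.72) than that array (5.76), so sex stays open, as does age, the difference the design names, which was not tested.

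Sarcomere genes were higher at P28 than at P12. A larger share of newly differentiating myoblasts is argued against as the whole cause only weakly. Myog, Mymk and Mymx changed by a mean of -0.73 (SE 0.27), but of the 3 only Mymx fell past the threshold and 0 rose. All 3 stand in the fixed list of differentiation and fusion and had been seen, so this is no independent test. All 16 genes of an adult fibre list rose (mean 2.56, with Pvalb at 12.87 and Acta1 at 13.42) and 2 of 5 developmental genes fell (mean -0.85), 15 and 5 of them above the median of all probe sets at P1 and P12. This difference of 3.41 restates the pattern, because all these genes stand in the fixed lists, and it lends no support to RNA of mature fibres in the P28 sorts. That explanation stays open, as the filters and the GFP gate would remove intact fibres but were not tested for free RNA, and so do age, muscles and a possible batch.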

How the results depend on the processing

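The fits with the Gapdh 3' to 5' covariate or the array set and the exact test of all list means were chosen after the data were seen, and the other alternatives were planned. Where a value changed, the cause was not tested unless stated. Median centring, fits of the 2 ages alone, all probe sets and leaving out _x_at and _s_at probe sets moved no count of changed genes by over 1.5 times. Of the results for named genes and lists, 5086 and 1228 kept their direction and side of the threshold, 251 and 117 lost and 79 and 18 gained a call, and 4 genes reversed. In 155 of those counted as kept (53 for lists, 102 for genes) the sign changed with no call in either setting. The count for P12 against P1 was 2601 with array weights, 1911 with the 3' to 5' covariate, 2163 with array set as a block and 128 within array set 1. At an adjusted p under 0.01 the counts were 375 (P12 against P1), 3607 (P28 against P12) and 4630 (any age). At a log2 change of at least 1 they were 270, 1710 and 2024, and 68 and 64 genes changed in both steps in the same and opposite directions, fewer because both thresholds are stricter. With P12 arrays divided between the steps, the means were 181.7 and 113.8, with fewer arrays in each step. With the replicate number as a block the counts were 1428, 6004, 6957 and, at any age, 7413, and this check changed 3 list calls. Replicate numbers of P28 did not pair with the other ages (correlations from -0.09 to 0.13).

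With an estimated correlation no list was called. This setting changes p alone, and the calls of the cell cycle list (mean changes 0.72, -1.17 and -0.46) ended with adjusted p of 0.273, 0.273 and 0.536 and those of the quiescent list (0.26, 0.54 and 0.80) with 0.536, 0.541 and 0.446. With array set as a block as well, both first-step values (0.72 and 0.26) had adjusted p = 0.433. The quiescent list in P12 against P1 changed by 0.26 without dim probe sets (adjusted p = 0.059) and by 0.08 after quantile normalization (0.14). Pax3 (0.30, adjusted p = 0.0338) and Cdkn1b (0.80, adjusted p = 0.000681) reversed in P28 against P12 with the mean of their probe sets, which differ in direction. Col15a1 in P28 against P12 (0.005, adjusted p = 0.988) and Notch3 in P28 against P1 (0.61, adjusted p = 0.0371) reversed with the 3' to 5' covariate. In the exact test of all list means, the arrays of the 2 ages did not overlap for 5 of 17, 21 of 21 and 19 of 22 called lists, and the smallest adjusted p was 0.0543.

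Leaving out each array in turn gave 639 to 1351 genes in P12 against P1, lowest without P12 replicate 4 (639), P1 replicate 4 (646), P12 replicate 1 (655) and P1 replicate 3 (678). It gave 4580 to 5638 genes in P28 against P12, 5539 to 6482 in P28 against P1, 5955 to 7203 at any age, and 172 to 389 and 165 to 431 in both steps. The array means of the cell cycle list then changed by 0.58 to 0.81 and -1.32 to -1.04 in the successive steps, and those of the quiescent list by 0.46 to 0.58 in P28 against P12 and 0.71 to 0.89 in P28 against P1. None of these passed after adjustment. In the first step the exact p was 0.0286 to 0.0571, and with P28 it could not pass, as 3 against 3 or 4 against 2 arrays give no exact p under 0.1 or 0.0667. Calls of named genes were lost 150 times, 106 of them in P12 against P1. Genes near the background of 3.36 to 3.64 have changes that the signal over background limits.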

Other observations

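The tests of bone marrow genes and of regrouped arrays were chosen before their results were seen, and the probe sets singled out were chosen after their values were seen.

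Genes of 3 kinds of bone marrow precursor were measured at P28 and P12, as granule and erythroid genes were among the largest P28 increases. Of 7 genes of granulocyte precursors and granules, 6 rose, among them the granule proteins Ltf (2.73 ± 0.39, to 8.59), Prtn3 (2.17 ± 0.28, to 6.64) and Ctsg (1.81 ± 0.33, to 6.11), and Chil3 (3.12 ± 0.75, to 7.96). Of 7 measured genes of erythroid precursors, 6 rose, with carbonic anhydrase Car2 up by 3.34 ± 0.41 (to 10.20) and Car1 by 1.80 ± 0.32 (to 6.32), while the transferrin receptor Tfrc (9.22 and 9.24) did not pass. Of 8 B cell precursor genes 3 rose, Ebf1 (1.30 ± 0.24, to 7.24), Vpreb1 (0.92 ± 0.24, to 5.91) and Vpreb3 (0.90 ± 0.19, to 6.14), and Rag1, Rag2 and Dntt did not pass.

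RNA of granulocyte and erythroid precursors of the marrow in the P28 sorts is a candidate explanation that these counts (6 of 7 and 6 of 7) leave open, and for B cell precursors the count (3 of 8) decided neither way. Of these lists 1, 5 and 1 genes were above the median of all probe sets (5.54) at P1 and P12, and 0 stand in another list. The GFP gate would remove such cells, and age, the muscles dissected, which include intercostal muscle, and a possible batch cannot be told apart by this design.

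Regrouping the arrays of 2 ages into groups of the same sizes gave as many changed genes as the real ages only for the real split, 1 of 35 in each comparison. This is the smallest share that 35 splits can give, so it argues against chance without excluding it. The real counts and the highest others were 1195 and 68 for P12 against P1, 5716 and 2497 for P28 against P12, and 6656 and 2699 for P28 against P1. The 68 genes came from the split of array set 1 against array set 2, and the 2 other maxima came from splits that kept the 3 P28 arrays together, with P12 replicate 4 or P1 replicate 1. Of 100 drawn splits of the 11 arrays, the real one included, 1 gave as many genes at any age (7098, highest other 5122), 1 as many in both steps in the same direction (308, highest other 0) and 1 as many in opposite directions (339, highest other 71). For the number of lists called, chance cannot be excluded, because 2 of 35, 2 of 35 and 3 of 35 splits gave as many. The real numbers were 17, 21 and 22, the highest others 18, 21 and 23, and the medians of the others 8.5, 12 and 13.5.

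A probe set that has no gene symbol here had a mean of 0.17 over the P1 and P12 arrays (-0.29 to 0.48), below the background controls, and of 6.35 at P28. A probe set of Ilkap was at 7.81 over P1 and P12 and 12.22 at P28, while another of that gene was at 8.90 and 8.67. The lowest value of an array was also higher at P28 (1.65 to 2.09) than at P1 and P12 (-0.79 to 0.48), and the labels do not say whether the P28 arrays were processed with the others.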
